A study of Homo sapiens with 6 samples.

How the data were processed

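Per the labels' protocols, the lines were grown in RPMI-1640 medium with serum, RNA was extracted with the GENEzol reagent, and stranded mRNA libraries were prepared with a TruSeq kit. The submitters' processing notes name Trimmomatic, Bowtie2 and the genome build hg38, with no role or version. The counting tool, the annotation release and the handling of reads that map to several places are not given in the sources used here. For each sample the authors deposited whole-number read counts per gene, which per the file headers are total exon reads, uniquely mapping exon reads and intron reads, with no normalization. Per the file headers the same files give TPM, and the values equal total exon reads over exon length scaled to a fixed sum, to within 5e-07. The authors also deposited a series table that its name calls raw counts but whose values are the same TPM rounded, with a largest difference of 0.005 from the sample files. It was used here as TPM in that check alone.

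The files paired 21463 gene identifiers (19922 protein coding) with symbols and hg38 positions, which were used as given. Total exon reads were the main values and ranged from 21222102 to 29366085 per library, of which 90.8% to 91.7% mapped uniquely. A count of 0 was read as up to 3 counts, 0.0985 to 0.145 CPM per library after TMM scaling. Ratios of 2 libraries in which 1 held few reads carry a 95% interval from the exact binomial method (Clopper-Pearson), which covers counting error only. A fold against a library at 0 reads was computed against the floor of 3 counts in that library and is a lower bound.

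Libraries were grouped by the labels: 3 parental and 3 resistant, with the cell line as the pair and as the replicate. The comparison of resistant with parental libraries used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, genes kept by filterByExpr (minimum count 10, minimum total 15) and the cell line as a block, which leaves 2 residual degrees of freedom. It was run on 13541 genes, with a common dispersion of 0.149 (a biological coefficient of variation of 38.6%). A fit with separate terms for gefitinib and osimertinib selection gave the change in the gefitinib-selected lines and its difference from the change in H1975, with 1 residual degree of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors were taken from the fitted log2 fold change and its F statistic.

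Before the data were examined, 27 gene lists were fixed: EGFR family receptors and ligands, other receptor tyrosine kinases and ligands, ERK pathway output, epithelial markers, mesenchymal markers, cholesterol synthesis, fatty acid synthesis, glycolysis, oxidative phosphorylation, NRF2 and glutathione, cell cycle, type I interferon response, antigen presentation and checkpoints, NF-kB inflammatory genes, YAP/TEAD targets, drug efflux transporters, the BCL2 family, neuroendocrine markers, alveolar lineage, squamous markers, stem cell markers, endoplasmic reticulum stress and ATF4 targets, hypoxia, leukocyte markers, endothelial markers, fibroblast markers and reference genes. Of 534 listed genes 533 were matched, 3 of them by identifier; IGF2 was matched to a row that the files name IGF2_1, and SOD2 was not matched. Members kept by the filter were counted as measured. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry of limma 3.58.1 on voom values, adjusted over the lists. Each list's members were also adjusted over the list alone.

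Within a line, the log2 ratio of TMM-scaled CPM was taken with 1 CPM added to both libraries, and genes with at least 10 CPM in 1 of the 2 libraries were counted at 2-fold or more. A list's median log2 ratio was set against 10000 random lists of the same size, matched in 20 bins of mean expression. The random lists hold unrelated genes, so their range can be too narrow for a list of co-regulated genes. The overlap of the lines was set against the number expected if the lines were independent.

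The named genes were also chosen by a rule fixed before the data were examined. It took, for the comparison over the lines, up to 10 genes in each direction that passed, filled up with genes of at least 10 CPM in 3 or more libraries that had the largest smallest log2 ratio over the 3 lines in 1 direction. It took the 10 highest and 10 lowest genes of each line and up to 4 members of each list by mean log2 ratio, with 4 more in a line whose list median lay outside the random range. It took EGFR, MET, AXL, ERBB2, ERBB3, HGF, CD274, BRAF, PIK3CA, NF1 and RB1 in every library, and up to 5 genes in each direction that passed between the drugs in edgeR, of which there were 0. Some genes that the rule took are not reported here.

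The alternatives fixed before the data were examined were relative log expression factors, no filter or a minimum of 10 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2 TPM with 1 or 0.1 added, no replicate block, each line left out, and a threshold of 0.1. For the values within a line they were 0.1 or 5 CPM added, a minimum of 1 or 50 CPM, library size alone, relative log expression factors and TPM. Uniquely mapping exon reads as the input were added as an alternative chosen after seeing the data.

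The edgeR tests were tested on simulated data with known changes, drawn from the mean levels and sizes of these libraries with 50 genes at each of 4 fold sizes. Dispersion followed the trend on expression fitted to these data (common value 0.149), with no spread between genes of the same level. The fit to the real counts found such a spread, so the simulated shares can be too high. Of the genes changed 2-fold, 22% were called between the states, as were 92% of those changed 4-fold. All of those changed 8-fold or 16-fold were called, with 6 unchanged genes called among 13318. For the change in the gefitinib-selected lines 6%, 74%, 96% and 98% were called at 2, 4, 8 and 16-fold, and for the difference between the drugs 4%, 14%, 44% and 75.5%. With a dispersion of 0.01 all genes were called for the states and the gefitinib change, and for the difference 66% at 2-fold and all from 4-fold. Intron reads and gene order along the chromosomes were used in the closing section alone, with the GC content of each gene's longest transcript in GENCODE release 44. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and drew the figures.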

Results

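Messenger RNA was sequenced from 3 human non-small cell lung cancer lines with EGFR mutations, each as 1 parental library and 1 library of a subline selected for resistance to an EGFR kinase inhibitor, 6 libraries in all. HCC827 and PC9 carry the deletion labelled E19Del and were selected with gefitinib, a reversible inhibitor of the EGFR kinase. H1975 carries L858R/T790M and was selected with osimertinib, a covalent inhibitor that also acts on the T790M receptor. Per the labels, the drug was raised stepwise over 90 days, and the half-maximal inhibitory concentration was 0.016 to 0.07 µM in the parental lines and 4.288 to 12.485 µM in the resistant ones. The libraries held 28140012 (HCC827 parental), 29366085 (HCC827 resistant), 21222102 (PC9 parental), 24463011 (PC9 resistant), 21249637 (H1975 parental) and 28895315 (H1975 resistant) exon reads over 21463 genes. A count of 0 allowed a level of up to 0.0985 to 0.145 CPM (read counts scaled to TMM-adjusted library size), depending on the library, and intervals and floors cover counting error only. Each line has 1 library per state, so values within a line have no replicate and no p-value, and the 3 lines are the replicates of the comparison of states.

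Across genes, the 2 libraries of a line resembled each other more than they resembled libraries of other lines. Pearson's r of log2 CPM across 13541 genes was 0.899 between the HCC827 libraries, 0.978 between the PC9 libraries and 0.970 between the H1975 libraries, against 0.771 to 0.849 between libraries of different lines. The log2 ratios of resistant to parental were weakly related across the same genes, with r = 0.17 for HCC827 and PC9, 0.11 for HCC827 and H1975, and 0.01 for PC9 and H1975; genes are not independent replicates.

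The first comparison set the resistant against the parental libraries over the 3 lines, to ask which genes differed with resistance whatever the line or drug. EGR1 (ENSG00000120738, hg38 chromosome 5, 138465490 to 138469315), an immediate-early transcription factor induced by ERK signalling, was lower in the resistant library of all 3 lines: from 66.9 to 0.637 CPM in HCC827, from 22.1 to 1.38 CPM in PC9 and from 11.3 to 3.28 CPM in H1975. IGFBP7 (ENSG00000163453, hg38 chromosome 4, 57030773 to 57110385), a secreted IGF-binding protein, was higher in all 3, from 12.5 to 55.4 CPM in H1975 and from 0.679 to 10.1 CPM in PC9. In HCC827 its resistant-to-parental ratio of 902 rested on 2 parental reads (95% counting interval 249 to 7455). SORL1, a sorting receptor, had log2 ratios of −4.62 in HCC827 and −1.63 in H1975, and was at least 35.4-fold lower in PC9, where 92 parental reads stood against 0.

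None of the 20 genes chosen for the size of their smallest difference over the 3 lines in 1 direction passed the edgeR test (adjusted p = 0.903 for each), and 15 passed with DESeq2. The fitted log2 fold change (± SE, n = 3 lines) was 4.46 ± 1.51 for IGFBP7, 2.34 ± 0.37 for the filamin-binding RFLNB, 1.77 ± 0.28 for SELENOM, a selenoprotein of the endoplasmic reticulum, and 2.04 ± 0.41 for AHRR, the repressor of the aryl hydrocarbon receptor. It was 1.85 ± 0.35 for AKR1C1, an aldo-keto reductase, and the complement protease C1S had log2 ratios of 1.62, 1.54 and 1.06 in HCC827, PC9 and H1975. The fitted value was −4.06 ± 1.10 for EGR1 and −2.27 ± 0.39 for the sulfotransferase CHST6. The size depended on the lines used: it was 2.86 for IGFBP7 and −2.86 for EGR1 without HCC827, and 6.33 and −5.29 without H1975. The other higher genes were MATN2, PKD1P1, RCN3 and ANXA8, and the other lower ones TFPI2, SYT12, PEG10, F2RL1, TMEM45B, HS3ST1 and MPZL2. Only 2% of the PKD1P1 reads mapped uniquely, 55% of those of ANXA8, 57% of those of TFPI2 and 78% of those of MATN2, so their values are uncertain.

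**Figure D1:**
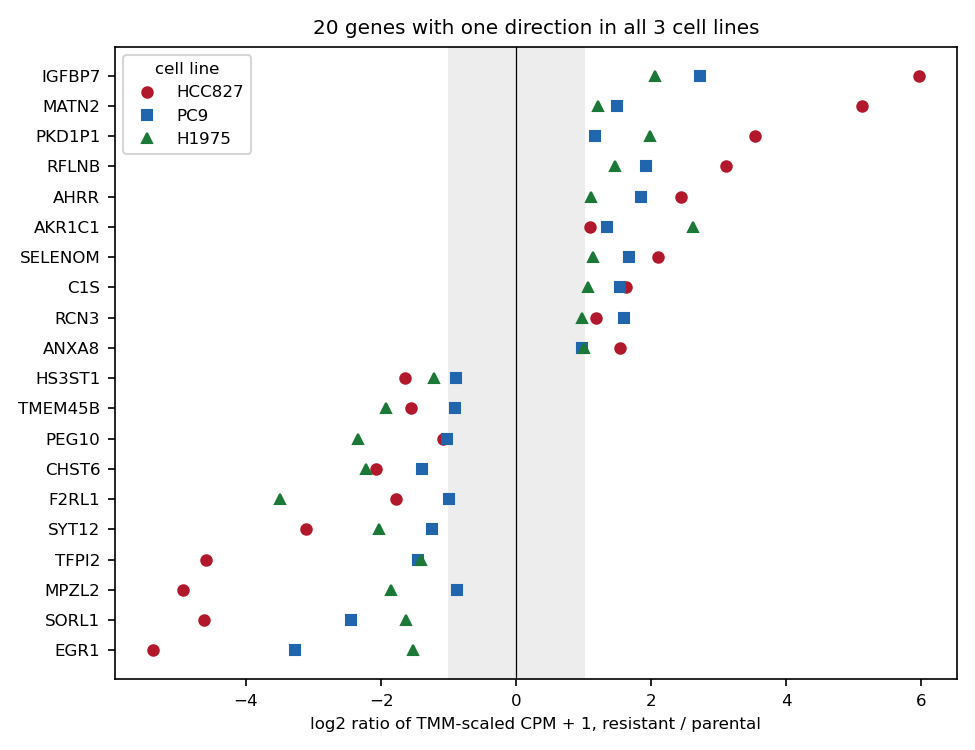
Log2 ratio of resistant to parental TMM-scaled CPM (1 CPM added) on the horizontal axis for the 20 genes chosen for the size of their smallest difference over the lines in 1 direction, 1 point per line (HCC827, PC9 and H1975); the grey band spans −1 to 1. EGR1 lies at −5.37, −3.27 and −1.52, IGFBP7 at 5.96, 2.73 and 2.06, and none passed the edgeR test over the lines, while 15 passed with DESeq2.

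Of the 11 measured EGFR family receptors and ligands, 6 were lower in all 3 resistant libraries and 1 was higher in all 3. EGFR (ENSG00000146648, hg38 chromosome 7, 55019021 to 55211628) went from 2383 to 145 CPM in HCC827, from 947 to 856 CPM in PC9 and from 389 to 224 CPM in H1975, log2 ratios of −4.03, −0.15 and −0.79. ERBB2 was lower in each, at −0.54, −0.36 and −0.46, and ERBB3 had −3.03, −0.41 and −2.31, with 55% of its reads mapping uniquely. The list was lower by camera (adjusted p = 0.035), and with an estimated correlation its adjusted p was 0.703. Of 23 other receptor tyrosine kinases and ligands, 5 were higher and 2 lower in all 3 lines (camera adjusted p = 0.384). MET, the hepatocyte growth factor receptor, had log2 ratios of −1.10, −0.17 and −1.14 in HCC827, PC9 and H1975, and AXL, the GAS6 receptor, had 6.19, 0.93 and −1.10. HGF was at 6.89 CPM in parental HCC827 and at most 0.212 CPM in the other libraries.

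Genes that report ERK signalling were mostly lower: 11 of the 19 measured members were lower in all 3 resistant libraries and none was higher in all 3. FOS, an immediate-early gene, had log2 ratios of −2.54, −1.96 and −0.89 in HCC827, PC9 and H1975. The ERK phosphatase DUSP6 had −5.14, −1.36 and −0.13, and SPRY4, a feedback inhibitor of receptor signalling, −2.86, −0.87 and −1.05. The member EPHA4 went the other way in HCC827 and H1975, with 3.39, −0.35 and 0.76. In HCC827, 10 members were at least 2-fold lower and 2 at least 2-fold higher. The list was lower by camera (adjusted p = 1.6e-05), and with an estimated correlation its adjusted p was 0.641. Among genes of the same pathways, BRAF had log2 ratios of −0.46, −0.16 and −0.38 with 59% unique reads, PIK3CA 0.23, −0.31 and −0.30, and NF1 0.55, −0.52 and −0.65. RB1 had 0.50, 0.20 and 0.10, and CD274, the checkpoint ligand PD-L1, 0.48, 0.81 and −0.97.

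Of 25 epithelial markers, 14 were lower in all 3 resistant libraries and none was higher in all 3. The adhesion molecule CDH1 had log2 ratios of −4.34 in HCC827, −0.50 in PC9 and −4.37 in H1975, and EPCAM had −5.23, −0.03 and −4.24. Of 23 mesenchymal markers, 8 were higher and 1 lower in all 3 lines; the matrix gene FN1 had 1.91, 2.62 and 0.59 and COL5A1, a fibrillar collagen, 5.64, 2.69 and 0.61. The epithelial list was lower (camera adjusted p = 6.4e-10) and the mesenchymal list higher (camera adjusted p = 2.53e-07). With an estimated correlation the adjusted p was 0.641 for each. The epithelial median in PC9 (−0.08) and the mesenchymal median in H1975 (0.00) lay inside the range of random lists.

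**Figure D2:**
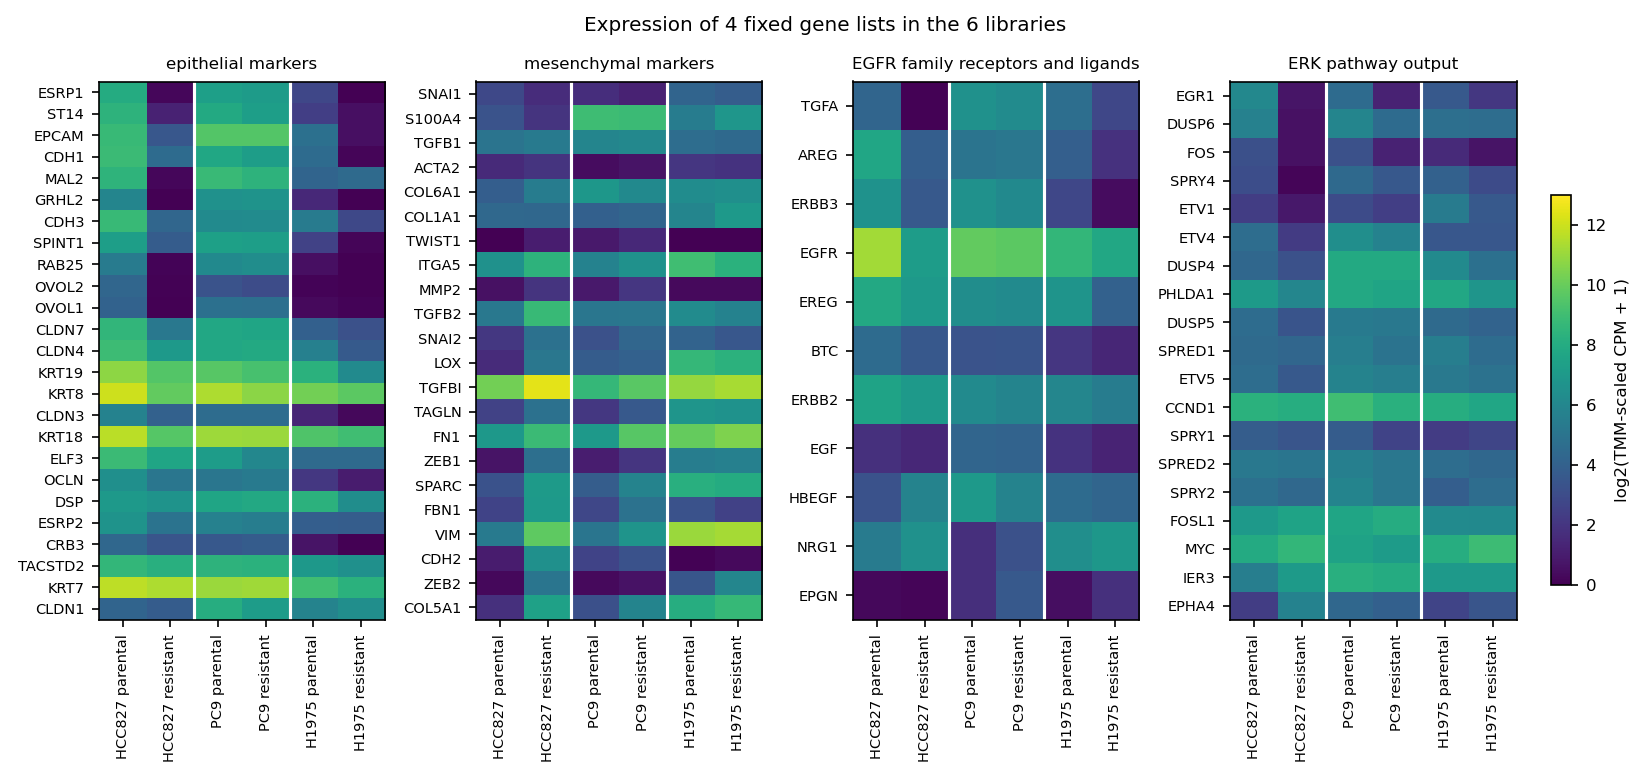
Heat maps of log2(TMM-scaled CPM + 1), from 0 (dark) to 13 (yellow), for measured members of 4 fixed lists (22 of 23 for the mesenchymal list; genes on the vertical axis) in the 6 libraries (horizontal axis; white lines part the cell lines). EGFR was at 2383 CPM in parental and 145 CPM in resistant HCC827, where ESRP1 was at 257 and 0.187 CPM.

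NF-kB inflammatory genes were higher by camera (adjusted p = 3.19e-06; 5 of 20 higher and 1 lower in all 3 lines; with an estimated correlation the adjusted p was 0.641). The cytokine IL32 was higher in each resistant library, with log2 ratios of 2.70, 2.34 and 3.07, and had the smallest p of all genes (7.34e-05, edgeR; adjusted p = 0.903). IL32 was under 10 CPM in both libraries of at least 1 line, so its level was low there. In PC9 the list median was −0.06, inside the random range, and CXCL8 was at −1.95. YAP/TEAD targets were higher by camera (adjusted p = 0.000233; 6 of 19 higher and 0 lower in all 3 lines; adjusted p = 0.703 with an estimated correlation). Without HCC827 their direction was lower, with an adjusted p of 0.941; ANKRD1, a member, had 4.73, −2.26 and 2.69. Type I interferon genes were higher by camera (adjusted p = 0.00583; 5 of 26 higher and 0 lower in all 3 lines; adjusted p = 0.809 with an estimated correlation), and MX1 had −0.24, 0.93 and 2.52. In HCC827 the interferon median was −0.72, with 12 members at least 2-fold lower and 0 higher. Without H1975 the direction of the interferon list was lower, with a camera adjusted p of 0.0575. Cell cycle genes were lower by camera (adjusted p = 0.000207; 9 of 30 lower and 0 higher in all 3 lines; adjusted p = 0.703 with an estimated correlation), as in the kinase BUB1 at −1.57, −0.31 and 0.06 (the H1975 value was −0.01 when scaled by library size alone). Alveolar lineage genes were lower by camera (adjusted p = 0.00111; 2 of 10 lower and 1 higher in all 3 lines; adjusted p = 0.641 with an estimated correlation), and the lineage factor FOXA1 had −0.73, −1.19 and −0.29. The estimated correlation of the alveolar list was −0.03, also below the preset 0.01, and camera gave an unadjusted p of 0.0645 with it. Without HCC827 the adjusted p of the cell cycle list was 0.113 and that of the alveolar list 0.143, and without H1975 that of the EGFR family was 0.0953. With no replicate block the adjusted p was 0.28 for the alveolar list and 0.201 for the interferon list.

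In all, camera with the preset correlation called 9 of 23 tested lists, 4 higher and 5 lower. With an estimated correlation it called 0, and fry, which tests whether a list's genes move on balance one way, called 0, as did its mixed form for changes in either direction. The lists that did not pass were cholesterol synthesis (camera adjusted p = 0.132), fatty acid synthesis (0.785), glycolysis (0.628), oxidative phosphorylation (0.0997), NRF2 and glutathione genes (0.765), antigen presentation and checkpoints (0.132), drug efflux transporters (0.31), the BCL2 family (0.76), squamous markers (0.743), stem cell markers (0.505), endoplasmic reticulum stress and ATF4 targets (0.335), hypoxia genes (0.0899), reference genes (0.583) and the receptor tyrosine kinases above. Measures of direction differed for fatty acid synthesis (median over members −0.12, mean 0.00, test lower) and for drug efflux transporters (median 0.36, mean −0.01, test higher). In 4 lists under 5 members were measured and no test was run: neuroendocrine markers (4 measured, 2 higher in all 3 lines), leukocyte markers (3 measured, 1 higher), endothelial markers (4 measured, 1 lower) and fibroblast markers (3 measured, 2 higher). In edgeR no member of any list passed over all genes, while DESeq2 called several, IL32 (adjusted p = 4.7e-17) and EGR1 (0.00117) among them. With edgeR p-values adjusted over the list alone, 1 gene passed in each of 3 lists: IL32 among the NF-kB genes, the keratin KRT17 among the squamous markers and the collagen COL6A3 among the fibroblast markers.

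The edgeR test called 0 of 13541 genes, with 502 at an unadjusted p under 0.05 where chance gives 677. limma-voom called 0, with 763 at an unadjusted p under 0.05, and DESeq2 called 58 (32 higher, 26 lower), with 923. Of these 58 genes, 55 lay on the same side in all 3 lines, 15 were among the 20 genes above, and 18 were under 10 CPM in every library of 1 group. In simulated counts, genes changed alike in all 3 lines were called by the edgeR test in 22% of cases at 2-fold, 92% at 4-fold and 100% at 8-fold. Genes of the same level were given the same dispersion there, which real genes do not have, so these shares can be too high for the real data.

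The next comparisons took the drugs apart. The matrix genes FBN1 and COL5A1 were higher in both gefitinib-selected lines. FBN1 had log2 ratios of 4.43 in HCC827 and 2.14 in PC9, against −0.76 in the osimertinib-selected H1975 line, and COL5A1 had 5.64 and 2.69, against 0.61. CEACAM6, an adhesion molecule of epithelial cells, went from 576 to 51.7 CPM in PC9. In HCC827 it went from 84.4 CPM to a level that rested on 2 reads, and in H1975 its log2 ratio was −0.38.

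No gene passed in edgeR for the change in the gefitinib-selected lines, with 595 at an unadjusted p under 0.05 and the smallest p for the mucin MUC5B (0.000174; adjusted p = 0.895). DESeq2 called 105 genes (92 higher, 13 lower; 942 at an unadjusted p under 0.05) and limma-voom 0 (856 at an unadjusted p under 0.05). No gene passed in edgeR for the difference between the drugs either, with 434 at an unadjusted p under 0.05 and the smallest p for PHLDA3 (0.000209; adjusted p = 0.967). DESeq2 called 72 genes (67 higher in the gefitinib contrast, 5 lower; 495 at an unadjusted p under 0.05) and limma-voom 0 (494 at an unadjusted p under 0.05). The FBN1 difference had an unadjusted p of 0.0179 in edgeR and an adjusted p of 1.00, while DESeq2 called it (log2 4.41, adjusted p = 0.0282). These fits had 1 residual degree of freedom, and with 1 osimertinib-selected line the drug, the EGFR mutation and the line cannot be told apart. In simulated counts, the edgeR test called 96% of genes changed 8-fold in the gefitinib-selected lines. It called 44% for the difference where the gefitinib-selected lines alone changed 8-fold. These shares can also be too high for the real data.

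Within HCC827, most epithelial markers were lower in the resistant library and most mesenchymal markers higher. MAL2, an apical transport protein, went from 347 to 0.187 CPM, the splicing factor ESRP1 from 257 to 0.187 CPM, and the membrane protease ST14 from 334 to 1.35 CPM. The secreted AGR2 went from 3241 reads to 0, at least 1050-fold lower. The cadherin CDH6 had a log2 ratio of 6.78, the teneurin TENM2 6.74, the endopeptidase MME 6.35, AXL 6.19 and the membrane-repair gene DYSF 6.16. Of 25 epithelial markers, 20 were at least 2-fold lower and 0 higher, and 18 of 23 mesenchymal markers were at least 2-fold higher (CDH2 at 5.50, the repressor ZEB2 at 4.77) and 2 lower.

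Other lists also stood apart from 10000 random lists matched on expression. The median log2 ratio of the YAP/TEAD targets was 1.53 (16 of 19 at least 2-fold higher, CTGF at 4.65 and ANKRD1 at 4.73), and that of the NF-kB genes 1.05 (CXCL8 at 3.86, IL6 at 3.06). The EGFR family median was −0.83, with AREG at −3.82, and the ERK list median −1.02. The receptor tyrosine kinase median was 0.50, with FGFR1 at 4.92, and that of the drug efflux transporters 0.71, although ABCC2 was at −4.49. Medians were also lower for cholesterol synthesis at −0.83 (INSIG1 −3.11, FDFT1 −2.56), fatty acid synthesis at −0.51 (SCD, the stearoyl-CoA desaturase, from 996 to 117 CPM), oxidative phosphorylation at −0.41, the cell cycle at −0.52 and interferon genes at −0.72 (IFI27 −4.35, BST2 −3.20). The reference genes had a median of −0.36, inside their random range (−0.38 to 0.33) but close to that of oxidative phosphorylation. The alveolar median was −0.62 (SFTA2 −4.40, NAPSA −3.28) and the squamous median −0.75 (KRT16 −2.63). The stem cell median was −0.56, outside the random range, and −0.41, inside it, when genes at 0 reads were set to the floor. NQO1, a quinone reductase induced by NRF2, was at −4.04 although the NRF2 median of −0.14 lay inside the range.

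Of 10298 genes with at least 10 CPM in 1 of the HCC827 libraries, 1078 were at least 2-fold higher and 788 at least 2-fold lower, 18.1% in all, and 76 and 93 passed 16-fold. The share of reads from mitochondrial genes was 3.32% in the parental and 6.62% in the resistant library. Higher genes made up 57.8% of those at 2-fold or more, but 50.2% when scaled by library size alone and 50.8% with TPM. Among genes with at least 50 CPM the share was 66.1%. Scaling by library size alone moved the median log2 ratio of all HCC827 genes from −0.01 to −0.11. The HCC827 count of 1866 was 943 among genes with at least 50 CPM.

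Within PC9, the resistant library had higher mesenchymal markers and cholesterol synthesis genes. FN1 went from 126 to 777 CPM, and 10 of 23 mesenchymal markers were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.80. Of 25 epithelial markers 1 was at least 2-fold lower, and their median of −0.08 lay inside the random range. The keratin KRT13 went from 102 to 1.17 CPM, complement C3 from 347 to 20.6 CPM, the aldehyde dehydrogenase ALDH3A1 from 200 to 25.2 CPM and the siderophore-binding LCN2 from 1182 to 227 CPM. KRT17 went from 15.2 to 142 CPM, and DOCK10, KISS1, NEURL1 and IGFN1 were also among the highest, with log2 ratios of 3.18, 2.95, 2.85 and 2.83. KRT81, CGB8 and CGB5 were among the highest too, with 56%, 50% and 40% unique reads, and SLX1B among the lowest, with 3%.

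In PC9 the cholesterol synthesis median was 0.41 (SQLE, squalene epoxidase, 1.74; MSMO1 1.43), the fatty acid synthesis median 0.16 (SCD 1.60), the interferon median 0.55 (OASL 1.90, IFI44 1.85) and the antigen presentation median 0.20 (HLA-B 1.78). The NRF2 median was 0.24 (AKR1C1 1.34), the YAP/TEAD median 0.16, although ANKRD1 was at −2.26, and the squamous median 0.44. The endoplasmic reticulum stress and ATF4 median was 0.18 (the asparagine synthetase ASNS 1.15) and the hypoxia median 0.19 (NDRG1 1.27). The ERK median was −0.53 and the cell cycle median −0.20 (TOP2A −0.57). Of 9911 genes, 240 were at least 2-fold higher and 170 lower, 4.14% in all, and the count of 410 was 268 with 5 CPM added in place of 1. Higher genes made up 58.5% of the 410, but 47.9% among genes with at least 50 CPM.

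Within H1975, epithelial adhesion genes were lower and interferon and inflammatory genes higher in the resistant library. CDH1 went from 22.4 to 0.131 CPM, EPCAM from 26.6 to 0.460 CPM and COBL, an actin nucleator, from 46.9 to 0.361 CPM, and 12 of 25 epithelial markers were at least 2-fold lower and 0 higher (median −0.78). TMEM255A, VGF and the mucin MUC16 were also among the lowest, at −4.64, −4.34 and −3.70. The mesenchymal median was 0.00, inside the random range, although ZEB2 was at 2.47 and the matrix gene POSTN went from 0 to 408 reads, at least 105-fold higher. IL32 went from 18.7 to 165 CPM, and TMEM47, ALPK2, OLR1, ABI3BP, the decoy receptor TNFRSF11B and CADM1 had log2 ratios from 3.08 to 3.72.

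The H1975 interferon median was 0.93, with 12 of 26 members at least 2-fold higher and 0 lower (MX1 2.52, OAS2 2.29, IFI44L 2.22). The NF-kB median was 0.81 (CCL2 1.71, CXCL5 1.84) and the antigen presentation median 0.56 (HLA-B 1.42), although CD74 was at −1.61 and NT5E at −2.09. The EGFR family median was −0.65 (EREG −2.69, AREG −2.09), the ERK median −0.34 (ETV1 −1.76, DUSP4 −1.43) and the receptor tyrosine kinase median −0.28 (MST1R −1.99). Of 9940 genes, 175 were at least 2-fold higher and 320 lower, 4.98% in all. Over the 3 lines, 35 of 69 medians lay outside the central 95% of random lists, where 3.45 were expected. That number takes the members of a list as independent. Their correlation estimated by camera reached 0.757 (cholesterol synthesis), so the expected number can be too low.

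**Figure D3:**
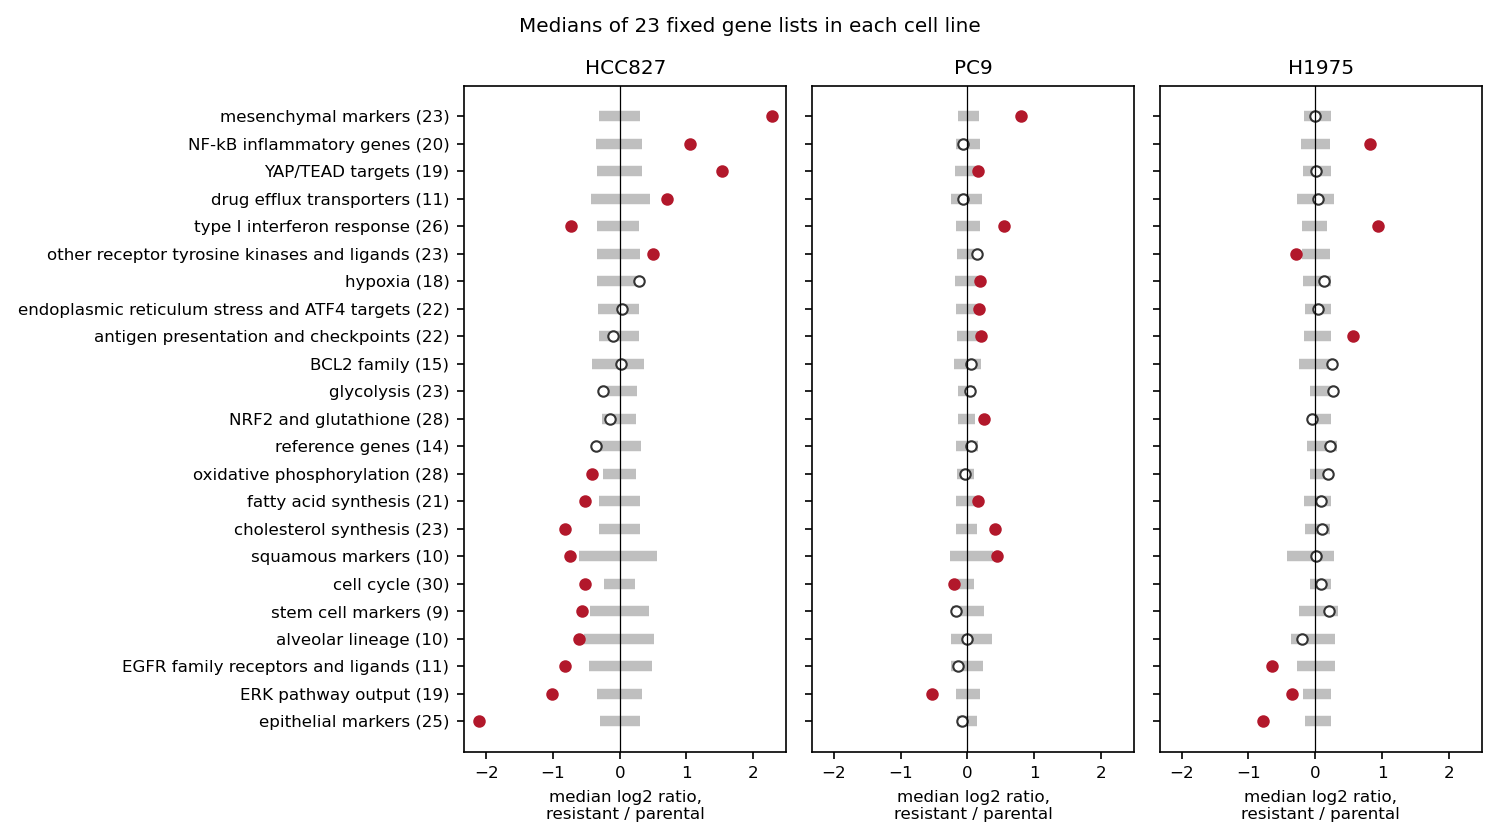
Median log2 ratio of resistant to parental (horizontal axis) for each tested list (vertical axis, measured members in brackets) in HCC827, PC9 and H1975; grey bars span the central 95% of 10000 random lists matched on expression, red filled points lie outside and open points inside. The medians outside numbered 16 in HCC827, 12 in PC9 and 7 in H1975, and the epithelial medians were −2.11, −0.08 and −0.78.

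The last comparison asked whether the same genes differed in the 3 lines. Among 8618 genes with at least 10 CPM in 1 of the 2 libraries of every line, 7 were at least 2-fold higher in all 3 resistant libraries (IGFBP7, AHRR, MATN2, C1S, PKD1P1, RFLNB and SELENOM), where 0.059 were expected if the lines were independent. At least 2-fold lower in all 3 were 5 genes (EGR1, TFPI2, PEG10, SYT12 and CHST6), where 0.145 were expected. HCC827 and PC9 shared 55 higher and 14 lower genes (8.47 and 5.71 expected), HCC827 and H1975 shared 23 and 57 (4.71 and 12.0 expected), and PC9 and H1975 shared 12 and 10 (0.752 and 2.64 expected), in each case with the genes shared by all 3 included. The expected numbers take every gene as equally likely to reach 2-fold. Genes that vary more than others in every line would raise the overlaps without a shared response, so the expected numbers can be too low. Co-regulated genes widen the spread around them, and the overlaps have no replicate check. The 12 genes shared by all lines became 7 with 5 CPM added in place of 1, all among the 12, and 25 with a minimum of 1 CPM, which held all 12.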

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

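The tests for cells of another line, for scaling and for early ERK genes alone were chosen after the result was seen, and the rules for reading the gene-copy, unrelated-line and immediate-early tests were made stricter after it. The results below were singled out because the list median of a line lay outside the random range on the side opposite to that of another line, and none of these differences between lines was tested. The other receptor tyrosine kinases and ligands had a median log2 ratio of 0.50 in HCC827 and −0.28 in H1975. Cholesterol synthesis genes had −0.83 in HCC827 and 0.41 in PC9, and fatty acid synthesis genes −0.51 in HCC827 and 0.16 in PC9. Type I interferon genes had −0.72 in HCC827, 0.55 in PC9 and 0.93 in H1975. Squamous markers had −0.75 in HCC827 and 0.44 in PC9.

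The 6 libraries can be split into 3 and 3 in 10 ways, so no share under 0.05 can be reached. The real split gave 0 genes and 9 lists, and the highest of the other splits gave 404 genes and 13 lists. With 0 genes in the real split, all 10 splits gave at least as many by construction, which decides nothing. At least as many lists came from 6 of the 10, the real one included. The 404 genes came from the 2 splits in which the fit compares the HCC827 pair alone, which points to a structure of the samples, a wider gap between the HCC827 libraries than between those of the other lines. Of the 4 splits that part all pairs, each gave 0 genes, and the real one gave the fewest lists, 9. The others, which put 1 resistant library among the parental ones, gave 10, 10 and 13 lists. The number of lists called thus does not set the real split apart.

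For the lower epithelial and higher mesenchymal genes of the HCC827 resistant library, cells of PC9 or H1975 in it are argued against: genes abundant in the other line and under 1 CPM in parental HCC827 stood at a median of 0.0336% of their PC9 level (23 genes, highest 44.4%) and 1.29% of their H1975 level (6 genes, highest 106%), where at least 50% would be needed. A few abundant transcripts shifting the scaling are argued against as well, since the epithelial median was −2.11 with TMM, −2.10 with relative log expression factors and −2.21 with library size alone. A library of an unrelated line stays open. Of the genes specific to parental HCC827, 71.4% kept at least 25% of their level (5 of 7, 95% Clopper-Pearson interval 29 to 96.3). For genes low in PC9, the share kept was 29.7 points above that of an unrelated line, H1975. For genes low in H1975 it was −4.76 points from that of PC9. A change of state that lowers genes of parental HCC827 would lower these shares too, so the second comparison cannot decide. The library's r with parental HCC827, 0.899, was above every r between lines (0.771 to 0.849). A change of state with gefitinib selection is the explanation that the design offers, and it may hold as a hypothesis alone, since 1 library per state cannot tell it from the unrelated line.

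Genes on 2 stretches of chromosome were lower together, on chromosome 7 in HCC827 (44796680 to 66958551, 31 of 38 genes lower, median log2 ratio −0.64) and on chromosome 18 in PC9 (21650897 to 80147523, 101 of 104 lower, median −1.07). On chromosome 7 most of the drop lay in 12 adjacent genes from COBL to CHCHD2, EGFR among them (−5.08 to −1.68, singled out after their values were seen), while the other 26 had a median of −0.48 with 19 lower. Lower genes lying side by side by chance are argued against by 0 of 1000 shuffles of the gene order on either chromosome (lowest windows of 20 genes −2.03 and −1.30, farthest shuffled ones 1.27 and 0.55), and GC content or gene length by window medians of −1.87 and −1.23 after that trend was removed. For chromosome 18, 20 weakly expressed genes that were not used to find the stretch had a median of −0.90 (16 lower). A loss of gene copies in PC9 would give this, and so would lower expression across the stretch. For chromosome 7, 9 weakly expressed genes had a median of −0.83 with 5 lower, and only 2 of them, both lower, lay among the 12 genes. A loss of gene copies there could include EGFR. On neither stretch can such a loss be told apart from lower expression, since DNA was not analysed here.

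ERK pathway genes were lower in all 3 lines, with medians of −1.02, −0.53 and −0.34 in HCC827, PC9 and H1975. EGR1, FOS and other early members alone do not account for it, since 13 delayed members had medians of −1.02, −0.59 and −0.34. These lay below the range of random lists in 3 of 3 lines, with 12, 12 and 9 of the 13 lower. The 13 are part of the same list of 19, so they are no separate evidence that ERK genes were lower. Harvest or handling that lowers immediate-early transcripts stays open for those early members: 20 other immediate-early genes had medians above 0 in 3 of 3 lines (0.08, 0.04 and 0.13), but inside the range of random lists, with 8, 9 and 8 of the 20 lower. Lower ERK signalling in the resistant cells may be the reason, a hypothesis that was not tested, since the RNA levels weighed here are its readout and phosphorylated ERK was not measured here. Whether inhibitor was present at harvest is not given in the sources used here and stays open.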

How the results depend on the processing

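The edgeR count of 0 genes between the states was also 0 with every alternative run except DESeq2 (58 genes), and the cause was not tested. For the gefitinib-selected lines DESeq2 gave 105 and for the difference between the drugs 72, the other alternatives 0. With no replicate block, which ignores the pairing by line, the count was 0, with 47 genes at an unadjusted p under 0.05 against 502 with the block. Leaving out each line in turn gave 0 to 0. The contrasts between drugs were not run with a line left out, since no residual degree of freedom remains without a gefitinib-selected line. Uniquely mapping exon reads, the alternative chosen after seeing the data, gave 0 genes and 9 lists.

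Of 20 named genes in the fit over the lines, 224 of 239 alternative values kept their direction and their side of the threshold, and 15 passed it, all with DESeq2 (smallest adjusted p 3.37e-05); 0 changed direction. The 9 lists called by camera became 0 with an estimated correlation. They were 7 with no replicate block, and 11 to 12 with each line left out, of which 6 without HCC827, 9 without PC9 and 7 without H1975 were among the 9 in the same direction. Lists that changed direction with a line left out were YAP/TEAD targets (adjusted p from 2.56e-06 to 0.941), cholesterol synthesis (0.000273 to 0.0245), squamous markers (0.0282 to 0.33) and type I interferon response (1.05e-20 to 0.0575). Cholesterol synthesis was higher without HCC827, at 0.000981. Of 161 list values, 134 kept direction and side, 14 no longer passed, 9 newly passed and 4 changed direction; the causes were not tested.

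Within lines, the HCC827 count of 1866 genes was 943 among genes with at least 50 CPM. The PC9 count of 410 was 268 with 5 CPM added, 729 with a minimum of 1 CPM and 140 with 50 CPM, and the H1975 count of 495 was 884 with 1 CPM and 187 with 50 CPM. The 12 genes shared by 3 lines were 7 with 5 CPM added and 25 with a minimum of 1 CPM, and 31 to 101 genes were shared with a line left out. A higher minimum tests fewer genes, a larger added value shrinks ratios and a line fewer is a looser demand, by construction. Of 3781 alternative values of named genes within lines, 3112 stayed within their interval, 669 moved beyond it and 0 called ones changed direction; of 1977 at 2-fold or more, 1914 remained so. Depth limits genes near 0: a count of 0 allowed a level of up to 0.0985 to 0.145 CPM.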

Other observations

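The tests described here were not planned, and the genes named in this part, except COBL, CDH3, NEURL1, IGFN1 and LCN2, were chosen after their values were seen. HCC827 and PC9, both selected with gefitinib, shared higher levels of GPNMB, a lysosomal glycoprotein, with log2 ratios of 3.13 and 2.13 against −2.90 in H1975, and of the tubulin TUBA1A (4.66 and 2.41, against 0.49), NEURL1 (2.95 and 2.85, against −0.92) and IGFN1 (6.19 and 2.83, against 0.43). They shared lower levels of ID1, an inhibitor of differentiation factors, at −3.51 and −2.09, against −0.28 in H1975. HCC827 and H1975 shared lower levels of COBL (−5.08 and −5.14, against −0.04 in PC9), the cadherin CDH3 (−4.46 and −2.58, against 0.07) and PROM2, a protein of membrane protrusions (−5.11 and −2.53, against −0.25). PC9 and H1975 shared lower levels of S100A9, a calcium-binding inflammatory protein (−1.68 and −3.32, against −0.47 in HCC827), the vesicle gene RAB27B (−1.83 and −2.25, against −0.50) and LCN2 (−2.38 and −1.51, against 0.38). COBL lies in the stretch of chromosome 7 that was lower in HCC827, and RAB27B in that of chromosome 18 in PC9.

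Intron reads were also counted on the stretches of chromosome that were lower. In HCC827 the median log2 ratio of intron reads on chromosome 7 was −1.14, with 30 of 37 genes lower (12 of 12 from COBL to CHCHD2, and a median of −0.71 over the others), and in PC9 that on chromosome 18 was −1.39, with 100 of 101 lower. The same stretches had exon medians of −0.17 in PC9 and −0.31 in H1975 for chromosome 7, and of 0.07 in HCC827 and −0.28 in H1975 for chromosome 18. The highest windows of 20 genes were on chromosome 1 in HCC827 (63774022 to 70439851, median 1.03), chromosome 19 in PC9 (34677639 to 36105106, 0.66) and chromosome 2 in H1975 (217799588 to 219236669, 0.63). The lowest in H1975 was on chromosome 12 (49976923 to 52192000, −0.82). Of 3 genes nearly silent in parental HCC827 and expressed in the other lines, CMBL and SNRPN were at 0 reads in both HCC827 libraries, and SRGN had 1 read in the parental and 4 in the resistant library.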
